A study of Mus musculus with 2 samples.

How the data were processed

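Gene expression was measured in single cells of the hypothalamus of newborn mice by Drop-seq, a droplet method in which each cell's RNA is caught on a barcoded bead and each captured molecule carries a unique molecular identifier (UMI). Per the labels' protocols, hypothalami of pups aged postnatal day 1 to 4 were dissociated with papain, viable cells negative for the dead-cell dye Sytox blue and positive for the red fluorescent protein tdTomato were sorted, and only the 3' ends of transcripts were amplified for sequencing. tdTomato came from the Ai14 reporter, which is switched on permanently in cells that express, or whose precursors expressed, Cre recombinase under the control of Sim1. The labels give the mice as CD-1, an outbred stock. The labels give 1 library of control cells (Sim1-Cre with tdTomato) and 1 library of Sim1 heterozygous cells (Sim1-Cre with tdTomato and 1 lost copy of Sim1), each pooled from 6 pups. With 1 library per genotype there is no replicate check: every difference below compares 2 libraries, not 2 conditions, and no p-value is given. The mix of ages and the genetic background of the pups could also differ between the pools, and this was not tested.

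The authors deposited tables of UMI counts per gene and barcode, 1 for each library and 1 merged table, which held identical cells and counts. Per the submitters' processing notes, bcl2fastq, Picard and STAR 2.6.0b were used with the mouse build mm10, and Seurat 3 is named as well, without a stated role. The gene annotation, the counter, its use of strand and the rule by which barcodes were taken as cells are not given in the sources used here. The deposited tables held 24905 genes and 5283 barcodes with 11922773 UMIs in all. Of the gene symbols, 23481 (94.3%) were found in GENCODE M21, from which gene types and mm10 coordinates were taken.

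Barcodes with under 300 genes (1 control, 22 Sim1 heterozygous) were left out, and the limit of 20% mitochondrial UMIs removed none, since the highest value was 9.84%. Scrublet marked 7 of 5260 cells (0.133%) as doublets, too few for the caller to have worked, so doublets must be taken as largely still present. The cells kept were 2801 control and 2452 Sim1 heterozygous. They were clustered together without integration (log-normalised values, 2000 variable genes without Sim1, the Irx genes, sex-linked and mitochondrial genes, 30 principal components, 20 nearest neighbours, Leiden resolution 1), neurons were clustered again in the same way, and clusters were named only from fixed marker genes. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, igraph 0.11.9 and leidenalg 0.10.2.

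Levels are UMIs summed over cells and divided by the library's or class's total, times 1000000 (CPM). The log2 ratio is Sim1 heterozygous over control with a pseudocount of 1 UMI per library, for genes with at least 30 UMIs over both libraries (14443 in neuron-like cells and 14593 in all cells). Exact Poisson intervals were used for levels, conditional exact binomial intervals for ratios and Clopper-Pearson intervals for shares of cells, all at 95%, and these cover counting error only, not differences between animals or preparations. A count of 0 was given a limit of 3 UMIs, or 3 cells for shares. For shares of cells with a UMI, each cell was thinned to 856 UMIs, the lower quartile of the shallower library, which left out 156 control and 611 Sim1 heterozygous cells. On sums simulated as Poisson counts for the neuron-like comparison, the interval held the true ratio for 95.9% of 14199 unchanged genes. For genes changed by a known fold, it did so for 97.9% of 47 genes at 0.25-fold, 95.9% of 49 at 0.5-fold, 96% of 50 at 2-fold and 94% of 50 at 4-fold. This checks the computation only, since real UMIs of the same cell are not independent and the simulation leaves that out. Per library, the median cell had 1772 UMIs (control) or 1579 UMIs (Sim1 heterozygous).

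Before the data were examined, 32 gene lists, the marker genes and the rule for named genes were fixed. The rule names Sim1, Irx3, Irx5 and the other genes of their list, and in neuron-like cells the 12 genes higher and the 12 lower whose interval of the log2 ratio has its bound nearest to 0 farthest from 0. It names 6 and 6 by the same measure over all cells, and up to 4 members of each list, those with the most UMIs or the interval farthest from 0. Mitochondrial, ribosomal protein, sex-linked, haemoglobin and unnamed genes were taken as groups. The median log2 ratio of a list was placed among 10000 random lists of the same size matched on mean expression, as a description of these 2 libraries. Members counted as higher or lower differ by at least 1.5-fold. Alternatives changed the cell filter, doublet handling, scaling, pseudocount, low-count filter, thinning, clustering and the weights of the neuron clusters. Equal weights took in only the 12 neuron clusters with at least 20 cells in each library. Left out were the clusters led by Tcf7l2 and Lhx9, by Pmch and Parpbp, and by A230103L15Rik and Gm44559. Some list members are not reported here by name.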

Results

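Cells of the Sim1 lineage were profiled from newborn hypothalamus in 1 control library and 1 Sim1 heterozygous library. The control library had 2807 barcodes and 6525080 UMIs, and the Sim1 heterozygous library had 2476 barcodes and 5397693 UMIs. After filtering, 2801 control cells (median 1772 UMIs and 1207 genes) and 2452 Sim1 heterozygous cells (median 1579 UMIs and 1104 genes) remained. Neuron-like cells made up 2748 control cells (98.1%) and 2397 Sim1 heterozygous cells (97.8%), and the rest were 53 and 55 astrocyte or radial glia-like cells. The lower quartile of UMIs per cell was 1220 in the control library and 856.75 in the Sim1 heterozygous library, so the latter held more shallow cells.

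The study asks whether Irx3 and Irx5 are misexpressed in the paraventricular nucleus (PVN) when a copy of Sim1 is missing. Sim1, the transcription factor needed to form the PVN, was lower in the Sim1 heterozygous library, at 92.6 CPM (UMIs per 1000000 UMIs of the neuron-like cells) [84.6 to 101] against 114 [106 to 122] in the control, a log2 ratio of -0.30 [-0.47 to -0.13]. Irx3, a homeobox gene of the Iroquois family, was at 2.82 CPM [1.58 to 4.65] against 2.49 [1.42 to 4.05], from 15 and 16 UMIs, and no difference was detectable at this depth (log2 ratio 0.18 [-0.94 to 1.29]). Irx5, its neighbour in the same gene cluster, was at 1.31 [0.529 to 2.71] against 1.56 [0.747 to 2.87], from 7 and 10 UMIs, also with no detectable difference (log2 ratio -0.19 [-1.88 to 1.30]). In the PVN-type neurons no Irx3 or Irx5 UMI was counted in either library, in 212 control and 121 Sim1 heterozygous cells. The limit of 3 UMIs then lies at 6.04 and 12.5 CPM. In the control library that class was mostly the cluster led by Avp and Oxt, and in the Sim1 heterozygous library mostly the cluster led by Crh and Nr3c1.

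Sim1 lies on chromosome 10 from 50894754 to 50989152, Irx3 on chromosome 8 from 91798525 to 91802067 and Irx5 on chromosome 8 from 92357625 to 92376286 (mm10). The Sim1 part deleted in these mice is not given in the sources used here, so a 3' tag count may not check the genotype label. Among neuron clusters with at least 10 Sim1 UMIs, 11 were lower and 2 higher by CPM in the Sim1 heterozygous library. Only in the cluster led by Nrgn and Aldoc did the interval of the log2 ratio leave out 0 (-0.72 [-1.15 to -0.32]). Several others were close to no difference, such as the cluster led by Neurod6 and Nfib, lower by CPM but at a log2 ratio of 0.003 with the pseudocount. After thinning, a Sim1 UMI was found in 240 of 2592 control neuron-like cells (9.26% [8.17 to 10.4]) and 132 of 1813 Sim1 heterozygous cells (7.28% [6.13 to 8.57]). Unthinned, the shares were 19.1% and 16.3%. Thinned to the median depth they were 15.2% and 13.8%, a ratio of 0.911 [0.743 to 1.11], which holds 1. In glia-like cells, which should lack Sim1, no thinned cell had a UMI, 0 of 53 and 0 of 28, which allows up to 5.66% and 10.7%. Median depth was 1350 and 1334.5 UMIs in these glia-like cells and 1880 and 2121 UMIs in the neuron-like cells. Irx3 was found in 5 (0.193%) and 3 (0.165%) of the thinned neuron-like cells, and in 0.473% and 0.292% unthinned. Irx5 was found in 4 (0.154%) and 2 (0.11%), and unthinned in 0.291% and 0.292%. The cluster led by Hopx and Rprm, chosen as background for both Irx genes after the values were seen, had no UMI of either in 285 and 300 thinned cells (median depth 1448 and 1790 UMIs), which allows 1.05% and 1%. The shares in all neuron-like cells lie below these limits, and a cluster chosen after its values of 0 were seen could not have excluded background. The UMIs were not spread evenly. The cluster led by Nrgn and Aldoc held 8 of 16 control and 14 of 15 Sim1 heterozygous Irx3 UMIs, and 5 of 10 and 6 of 7 Irx5 UMIs. It was named after these values were seen and is deeper (median 2722 and 2539 UMIs) than neuron-like cells as a whole (1788 and 1609). Clustering without the 10 leading genes of every neuron cluster, of each library alone or of thinned cells gave no value for it. Glia-like cells could not serve as background for Irx3, with 3 of 53 (5.66%) and 1 of 28 (3.57%) thinned cells positive, and 43.7 CPM in the control library. For Irx5 it was 0 of 53 and 1 of 28. Of the genes near Irx3 and Irx5, Fto was at a log2 ratio of 0.09 [-0.21 to 0.38], Rbl2 at 0.19, Aktip at 0.22 [0.04 to 0.41] and Rpgrip1l, a ciliary gene, at 0.62 [0.37 to 0.86]. The 6 measured genes of this list had a median of 0.19, with 1 higher and 0 lower. Irx1 had 6 and 4 UMIs, Irx2 11 and 15, and Irx6 2 and 2, in control and Sim1 heterozygous neuron-like cells.

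**Figure D1:**
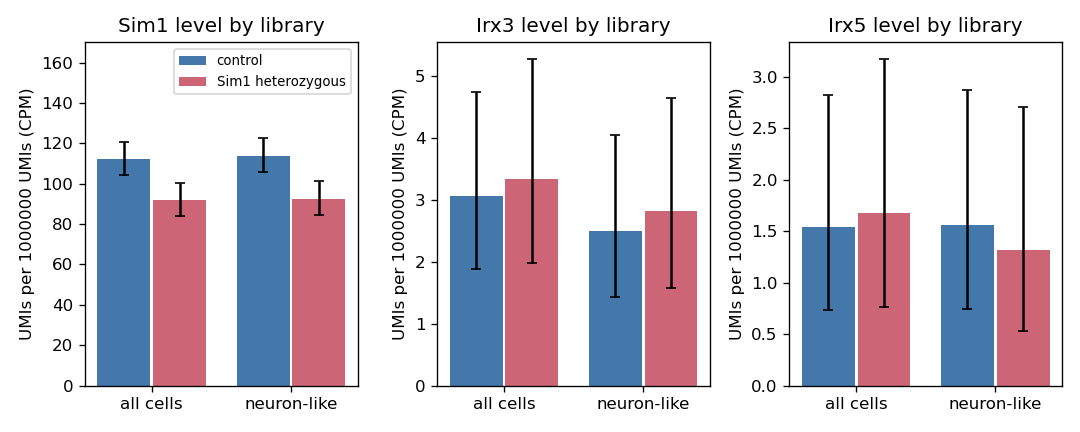
Levels of Sim1, Irx3 and Irx5 in CPM (vertical axes) in all cells and in neuron-like cells of the control and Sim1 heterozygous libraries, as bars with exact 95% Poisson intervals. Sim1 was lower in the Sim1 heterozygous library (92.6 against 114 in neuron-like cells), and the intervals of Irx3 and Irx5 overlapped.

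The 12 genes lowest in the Sim1 heterozygous library, by the bound of the interval nearer 0 in neuron-like cells, held Oxt, Avp, Pmch, Gh, Cga and Parpbp. Oxt, which encodes oxytocin, was 5.38-fold lower (481 against 89.4 CPM, log2 ratio -2.43 [-2.57 to -2.29]). Avp, which encodes vasopressin and lies beside Oxt on chromosome 2, was 3.75-fold lower (log2 ratio -1.91 [-1.94 to -1.87]). Pmch, the melanin-concentrating hormone gene of the lateral hypothalamus, was 3.56-fold lower (log2 ratio -1.83 [-1.90 to -1.76]). Gh, growth hormone of the pituitary, had 2178 UMIs in control neuron-like cells and 0 in Sim1 heterozygous ones, at least 602-fold lower against the limit of 3 UMIs, or 340-fold without the 3 cells with at least 50 Gh UMIs. Cga, the subunit shared by pituitary glycoprotein hormones, had 32 and 1 UMIs, a log2 ratio of -3.78 [-10.08 to -2.15]. Parpbp was at -2.51, but the annotation has it overlap Pmch on chromosome 10, and as the counter's use of strand is not given its reads cannot be told from those of Pmch. The other 6 of the 12 lowest were named only by clones. With 12 neuron clusters weighted equally the log2 ratios of Oxt and Avp were -0.36 and -0.04, and that of Pmch -0.23. This leaves out the cluster led by Pmch and Parpbp (13 Sim1 heterozygous cells), which held 8451 of 8718 control Pmch UMIs of neuron-like cells. Oxt, Avp and Pmch took part in the clustering, so the weighting does not separate cell number from level. Some other clusters were picked after their values were seen. In the cluster led by Crh and Nr3c1, Avp had 1216 and 106 UMIs (log2 ratio -3.47 [-3.78 to -3.19]). These lay in 35 of 96 and 24 of 98 cells, a ratio of shares of 0.672 [0.382 to 1.16]. Oxt there had 30 and 0 UMIs. In the cluster led by Nrgn and Aldoc, Oxt had 419 and 3 UMIs (-6.10 [-8.79 to -4.95]), but Avp was at -0.35 [-0.81 to 0.07]. Avp went the other way in the cluster led by Serp2 and Mrpl52, with 97 and 125 UMIs (204 and 495 CPM, 1.27 [0.88 to 1.68]). The 419 Oxt UMIs lay in 12 of 460 control cells, only 6 of them with 2 or more. As UMIs of the same cell are not independent, these intervals are too narrow. The cluster led by Avp and Oxt held 94.7% of control Avp and 83.5% of control Oxt UMIs, and there Avp was at 0.05 [0.01 to 0.08] and Oxt at -0.27 [-0.42 to -0.12], values not read as results because these genes define it.

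Cells rich in these hormones were counted without clustering, with cut-offs set after the values were seen. Cells with at least 10 Oxt UMIs made up 69 of 2801 control cells (2.46%) and 10 of 2452 Sim1 heterozygous cells (0.408%), a ratio of 0.166 [0.0760 to 0.323]. Cells with at least 10 Avp UMIs made up 110 (3.93%) and 26 (1.06%), a ratio of 0.270 [0.169 to 0.417]. After thinning, cells with at least 5 Avp UMIs made up 110 of 2645 (4.16%) and 21 of 1841 (1.14%). Free RNA of Avp was present, since 11 of 53 and 2 of 55 glia-like cells (median depth 1350 and 879 UMIs, against 1772 and 1579 in all cells) held an Avp UMI, but all glia-like cells together held 11 and 3. For Oxt it was 1 of 53 and 1 of 55 cells. Crh and Trh, other PVN hormone genes named after their values were seen, went apart over neuron-like cells. Crh was at a log2 ratio of 0.50 [0.29 to 0.71] and Trh at -0.46 [-0.67 to -0.25]. Within the cluster led by Trh and Fezf1, which Trh helps define, Trh was at 0.07 [-0.18 to 0.31]. Crh was lower in the cluster led by Nrgn and Aldoc, with 111 and 31 UMIs (-1.19 [-1.85 to -0.64]). The tdTomato sort can set the shares of hormone-rich cells, and its effect was not tested on its own.

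**Figure D2:**
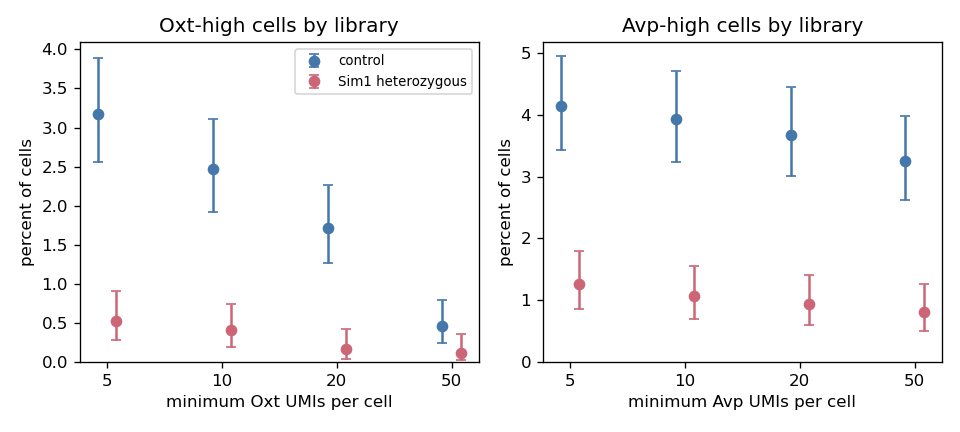
Percent of cells (vertical axes) with at least 5, 10, 20 or 50 UMIs of Oxt or Avp (horizontal axes) in each library, unthinned, as points with exact 95% binomial intervals. At 10 UMIs the shares were 2.46% and 0.408% for Oxt and 3.93% and 1.06% for Avp, control and Sim1 heterozygous.

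The genes higher in the Sim1 heterozygous library were led by Hspa8, a heat shock family chaperone, with 118 and 1562 UMIs (log2 ratio 3.98 [3.73 to 4.28]), higher in 14 of 14 neuron clusters with at least 10 UMIs. Cwc22, a splicing factor, had a log2 ratio of 1.85 [1.74 to 1.96] and was higher in 15 of 15. Hspa8 has near-identical pseudogenes, and H2-Bl (3.36) and H2-K2 (2.73) are annotated as pseudogenes of the major histocompatibility complex, so reads may have been split between copies. AA465934, annotated as a processed transcript, was at 2.51. Gpr83, an orphan receptor gene, was at 1.97, Cox6a2, a subunit of cytochrome c oxidase, at 1.85 and Tac2, which encodes neurokinin B, at 1.97 [1.32 to 2.78]. Dgkb, a diacylglycerol kinase, was at 1.45, Cpne9 at 1.62, Zfp703 at 1.95 and Tanc1, a synaptic scaffold gene, at 1.80, or 0.31 with clusters weighted equally. Processed pseudogenes as a group moved the other way: the 1806 measured had a median log2 ratio of -0.47 and took 4.31% of control and 3.02% of Sim1 heterozygous neuron-like UMIs. Protein-coding genes (11321) had a median of 0.08, ribosomal protein genes (95) -0.06, clone-named genes (255) -0.33 and mitochondrial genes (20) -0.17.

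Lists of PVN genes did not move as a block in neuron-like cells. Of 11 measured PVN transcription factors, 1 was at least 1.5-fold lower and 0 higher, with a median log2 ratio of -0.12 at percentile 7.2 of the random lists, and 0.02 (0 lower and 0 higher) with clusters weighted equally. The lower one was Otp, needed for PVN neurons to form, at -0.64 [-0.74 to -0.54], while Peg3 was at 0.28 and Zfhx4 at 0.52. Of 17 neuropeptide genes, 2 were lower (Oxt and Avp) and 3 higher, with a median of 0.21 at percentile 99.5, and with equal weights 0 were lower and 4 higher, with a median of 0.23. Nts (neurotensin) was at 0.86 and Adcyap1 (PACAP) at 0.73, but Nts was at -0.19 with clusters weighted equally. Of 16 receptors and signals of energy balance, 2 were higher and 2 lower, with a median of 0.17 at percentile 89.0. Cpe and Pcsk2, which process prohormones, were at 0.17 and 0.47, and Ntrk2, the BDNF receptor, at 0.31. Mc4r, the melanocortin receptor through which the PVN limits feeding, named after its values were seen, had 34 and 16 UMIs (-0.77 [-1.77 to 0.08]), not a detectable difference.

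Lists of neurons outside the PVN went in both directions. Of 6 thalamus genes, 4 were lower and 0 higher, with a median of -1.37, below all 10000 random lists. Tcf7l2, a Wnt pathway transcription factor, was at -1.81 [-2.02 to -1.61], Lhx9 at -2.15 and Gbx2 at -2.86 from 34 and 3 UMIs [-5.58 to -1.56]. Of 6 lateral hypothalamus genes, 3 were lower (Pmch, Lhx9 and Parpbp) and 2 higher, with a median of -0.98, also below all random lists. This rests on counting Parpbp beside Pmch: without Parpbp the median of 5 genes was -0.13, at percentile 14.2. With clusters weighted equally the medians of the full lists were -0.43 (1 lower and 1 higher) and -0.21 (1 lower and 1 higher). These values also leave out the clusters led by Tcf7l2 and Lhx9 and by Pmch and Parpbp, which were too small. The first of these held 933 of 1051 control Tcf7l2 UMIs, so the change is not due to weights alone. Of 8 mammillary genes, 3 were higher and 0 lower, with a median of 0.23 at percentile 95.9, and -0.03 (1 higher and 0 lower) with equal weights. Foxb1 and Lhx1, transcription factors of mammillary neurons, were at 0.82 and 0.86, and at -0.07 and 0.12 with equal weights. Of 7 arcuate genes, 3 were lower and 1 higher, with a median of -0.30 at percentile 3.4, or 0.645 among random lists without pseudogenes and unnamed genes, a reference chosen after pseudogenes were seen to differ, and with equal weights the median was -0.19 (2 lower and 1 higher). Ghrh, the hormone that releases growth hormone, was at -2.08 [-2.84 to -1.47] and Npy at 0.44. Of 4 ventromedial genes, 2 were higher and 1 lower, with a median of 0.16 at percentile 74.5, or -0.08 (0 higher and 1 lower) with equal weights. Fezf1 was at -0.89, or -0.14 with equal weights, and Nkx2-1 at 0.69. Of the dorsomedial list only Ppp1r17 (0.17) and Grp (-0.28) were measured.

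Lists of neuronal wiring and secretion had medians above 0. They were 0.22 for 36 synapse genes (percentile 99.98, 3 higher and 1 lower), 0.23 for 33 axon guidance genes (percentile 99.8, 5 higher and 2 lower) and 0.26 for 14 genes of peptide processing (percentile 99.8, 1 higher and 0 lower). With clusters weighted equally they were 0.14 (3 higher and 0 lower), 0.08 (2 higher and 3 lower) and 0.34 (4 higher and 0 lower). Gria2, an AMPA receptor subunit, was at 0.60, Syp (synaptophysin) at 0.56 and Nrxn3, a presynaptic adhesion gene, at -0.59. Nrp2, a semaphorin receptor, was at 0.82, or 0.08 with equal weights, Slit2 at 0.63 and Plxna4 at 0.55. Chga, a granin of secretory vesicles, was at 0.58 and Cadps2, which primes them, at 0.82. Of 17 immediate early and heat shock genes, 7 were higher and 0 lower, with a median of 0.22 at percentile 96.3 (8 higher and 1 lower, 0.30, with equal weights), among them Fos at 0.78, Jun at 0.73 and Jund at 0.63. For the same list over all cells, 4 were higher and 0 lower, with a median of 0.14 at percentile 85.0. The 16 pan-neuronal genes had a median of 0.04, with 0 higher and 0 lower. Of 8 glutamatergic genes, 4 were lower and 0 higher, with a median of -0.40 at percentile 0.11, and with equal weights 3 were lower and 2 higher, with a median of -0.12. Slc17a6, the vesicular glutamate transporter, was at 0.37, and Ebf1 and Ebf3, early B-cell factors, at -1.25 and -0.81. Of 4 GABAergic genes, 2 were lower and 1 higher (Gad2, at 0.82), with a median of -0.56 at percentile 3.68 (0.39 without pseudogenes in the random lists), or 0.07 (1 lower and 1 higher) with equal weights. Of 10 immature neuron genes, 4 were lower and 2 higher, with a median of -0.04, or 0.03 (2 lower and 2 higher) with equal weights. Sox11, a factor of young neurons, was at -0.76 and Igfbpl1 at -0.96. The 8 cycling genes had a median of 0.01 and the 7 measured mitochondrial-encoded genes -0.14.

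**Figure D3:**
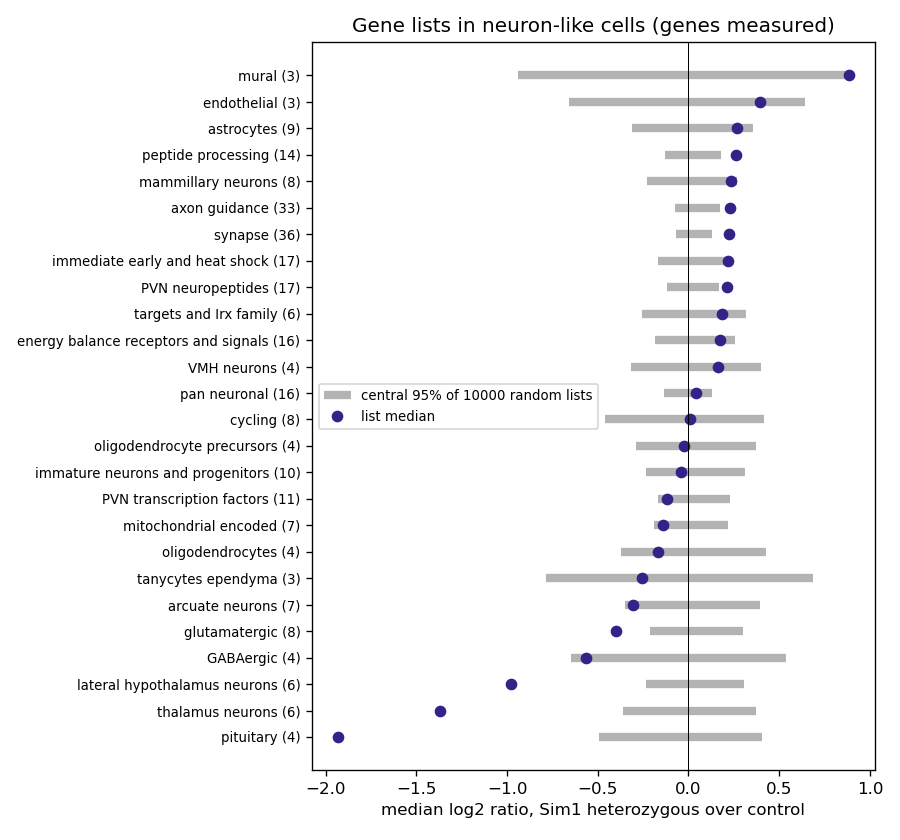
Median log2 ratio, Sim1 heterozygous over control, of each fixed gene list with at least 3 measured genes, except the sex-linked list, in neuron-like cells (points, horizontal axis), with the number of genes measured in brackets. Grey bars span the central 95% of 10000 random lists matched on expression. The pituitary (-1.93), thalamus (-1.37) and lateral hypothalamus (-0.98, with Parpbp) medians lay lowest.

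Markers of some other cell types also differed between the libraries. Of 4 measured pituitary genes, 2 were lower (Gh and Cga), and the median was -1.93, the same with Gh at its limit. Pomc, which is also on the arcuate list, was at -0.05. Over all cells, 4 of 4 fibroblast genes were lower, with a median of -3.03, among them Igf2, a growth factor, with 88 and 3 UMIs (-4.20 [-6.91 to -3.01]) and Col3a1, a collagen, with 47 and 1 (-4.31 [-10.61 to -2.73]). The fibroblast list had 575 UMIs over all cells and 275 in neuron-like cells. The others lay in the 53 and 55 glia-like cells, a class that may therefore hold other cell types too. UMIs of the same cell are not independent, so these intervals may be too narrow. Over all cells 5 endothelial genes had a median of -0.89 (3 lower, 0 higher) and 16 astrocyte genes 0.37 (4 higher, 0 lower). In neuron-like cells the medians were 0.27 for 9 astrocyte genes, 0.88 for 3 mural genes, 0.39 for 3 endothelial genes, -0.26 for 3 tanycyte or ependymal genes, -0.03 for 4 oligodendrocyte precursor genes and -0.17 for 4 oligodendrocyte genes. Microglia, erythroid and choroid plexus lists had 2 measured genes each in neuron-like cells. Among these, Aif1 of the microglia list was at 0.77, Bpgm of the erythroid list at -0.31, and Prlr and Enpp2 of the choroid plexus list at -0.46 and -0.25.

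Sex-linked genes differed between the libraries, and the sex of the pups is not given in the sources used here. Xist, expressed from the inactive X chromosome of females, was at -0.72 over all cells and Tsix at -1.38, while the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were at 0.45, 0.77, 1.03 and 1.02.

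Cell composition was compared for clusters that were found again without their leading genes. The cluster led by Trh and Fezf1 held 391 control cells (13.96%) and 174 Sim1 heterozygous cells (7.10%), a ratio of 0.508 [0.423 to 0.609], and 0.639 when clustered without the 10 leading genes of every neuron cluster. Astrocyte or radial glia-like cells made up 1.89% and 2.24%, a ratio of 1.19 [0.798 to 1.76]. The cluster led by Tac2 and Stk32a had a ratio of 1.08 [0.710 to 1.63], or 1.29 without leading genes. The cluster led by Emx2 and Fezf2 had a ratio of 0.796 [0.647 to 0.978], or 0.953 without leading genes and 1.41 when cells were thinned before clustering. The sizes of the clusters led by Avp and Oxt and by Tcf7l2 and Lhx9 are not compared, because these clusters were not found again without their leading genes.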

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

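The alternatives that weight neuron clusters equally for single genes, leave out Parpbp, leave out leading or neuropeptide genes, thin cells before clustering, remove the top doublet scores or leave out the shallowest clusters were chosen after the results were seen, as was the count of Oxt-rich and Avp-rich cells. Of 569 values of 101 results, 503 stayed within the counting interval of the reported value, 64 moved outside it, and 2 reversed, which was counted only where that interval left out no difference. Genes named by their size, with the list around Sim1 and Irx, moved in 15 of 258 values, 8 of them under equal weights. Other list members are not among these, and with equal weights Nts went from 0.86 to -0.19 and Foxb1 from 0.82 to -0.07. The equal weights also left out the neuron clusters with under 20 cells in a library, so weights and cells changed together. With them the sign changed for the medians of the mammillary (0.23 to -0.03), ventromedial (0.16 to -0.08), PVN transcription factor (-0.12 to 0.02), immature neuron (-0.04 to 0.03) and pan-neuronal (0.04 to -0.07) lists. PVN transcription factors were at 0.07 with a minimum of 100 UMIs, and pan-neuronal genes at -0.05 when thinned. The log2 ratio of Oxt was -2.60 as a mean over cells and -0.36 with clusters weighted equally. That of Avp was -1.95 with median-of-ratios scaling, -2.06 as a mean over cells and -0.0403 with equal weights. The ratio of shares of cells with Sim1 was 0.605 with at least 2 UMIs per cell but 0.911 [0.743 to 1.11] when thinned to the median depth, which holds 1, and the ratio of the Trh and Fezf1 cluster was 0.639 without leading genes and 0.649 when thinned first. The cluster led by Emx2 and Fezf2 reversed to 1.41 when thinned first, and the GABAergic list to 0.0691 with equal weights. Without pseudogenes in the random lists the arcuate and GABAergic medians lay outside the central 95%, and with them inside. For all of these the cause was not tested. Median-of-ratios scaling shifted neuron-like log2 ratios by 0.04. Of the 12 higher and 12 lower genes in neuron-like cells, 9 and 8 were also chosen with a minimum of 100 UMIs, and 10 and 10 with no minimum. Of the 6 and 6 over all cells, it was 5 and 2 with a minimum of 100 UMIs, which Igf2 and Col3a1 do not reach, and 6 and 6 with no minimum. Clustering each library alone, or without leading genes, gave no value for most clusters. At least 2 Irx5 UMIs were found in 2 of 2748 and 0 of 2397 neuron-like cells, a ratio of 0. Requiring 500 genes changed no thinned share, since the thinned cells all passed it. No paired analysis was possible because each genotype had 1 library. Depth limits what can be said of Irx3 and Irx5: with 15 and 7 UMIs in the Sim1 heterozygous neuron-like cells, ratios up to 2.44 and 2.46 lay within the counting intervals.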

Other observations

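All tests in this part were chosen after the results they bear on had been seen, and the genes and cell groups named here were picked from their values. Among further genes of neuron-like cells, Calb1, a calcium buffer, was at a log2 ratio of 1.19 [1.08 to 1.30], Atp2b4, a calcium pump, at 1.23 and Pde1c, a calmodulin-dependent phosphodiesterase, at 1.28. The homeobox genes Nkx6-1 and Lhx2 were at -2.16 and -2.03. In the cluster led by Nrgn and Aldoc, Irx3 had 8 control and 14 Sim1 heterozygous UMIs (5.38 and 14.5 CPM, log2 ratio 1.35 [0.07 to 2.89]), from 6 of 460 and 6 of 313 cells. Sim1 in the same cluster had 178 and 70 UMIs, a log2 ratio of -0.72 [-1.15 to -0.32]. This cluster was singled out from 16 cell groups, and UMIs of the same cell are not independent, so the Irx3 interval is too narrow. In its thinned cells, Irx3 was found in 2 of 443 and 3 of 282, a ratio of shares of 2.36 [0.270 to 28.2], which holds 1. Clustering without leading genes, of each library alone or of thinned cells gave no value for this cluster.

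Gh was present in the control library and not counted in the Sim1 heterozygous library, although the sort kept tdTomato-positive cells. Intact pituitary cells in the sort as the only holders of Gh UMIs are argued against. The 3 cells with at least 50 Gh UMIs held 43.1% [41.0 to 45.2] of 2205. Of the other 2798 control cells, 946 (33.8%) had a Gh UMI. These values cannot tell whether RNA released from such cells was the source of the rest. Gh expression that follows Sim1 is also argued against, because cell groups with little Sim1 had 1.14 times [0.929 to 1.38] the Gh CPM of the others with those 3 cells left out, and 0.622 times [0.510 to 0.752] with them, both above the bound of 0.5. Free RNA from pituitary tissue is a candidate explanation that stays open. Every control cell group had cells with a Gh UMI. Unthinned, these were from 22.7% (cluster led by Slc32a1 and Isl1) to 52.9% (cluster led by A230103L15Rik and Gm44559). With those 3 cells left out, glia-like cells had 1.54 times [1.01 to 2.25] the Gh CPM of neuron-like cells, and 0.869 times [0.571 to 1.27] with them. The value of 1.54 met neither bound set for it, and glia-like control cells were also shallower (median 1350 against 1788 UMIs). Of the other pituitary genes, Cga had 32 and 1 UMIs in neuron-like cells and Tshb 18 and 0 over all cells, while 2 of the 4 measured list members, Pomc among them, are also on other lists.

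By CPM, processed pseudogenes were lower and Hspa8 higher in the Sim1 heterozygous library in 16 of 16 cell groups, glia-like cells included, though in the shallowest group Hspa8 rested on 1 UMI against 0, a log2 ratio of -1.04 with the pseudocount. This is consistent with a difference between the libraries in reads or in how they were assigned to genes, and with 1 library each the library and the genotype coincide. Lower RNA of the parent genes is argued against: the median difference between a pseudogene and its parent was -0.64 [-0.77 to -0.42] over 266 pseudogenes of 121 parents. A heat shock response behind Hspa8 is argued against by a median only: the other 5 heat shock genes had a median of 0.0381 [-0.16 to 0.23]. The bound of 1 was first set for each of these genes, and the interval of Hspa1a, the highest at 0.60 [0.07 to 1.14], reached past it. It was moved to the median after these values were seen, and by the first rule the question was undecided.

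Cells rich in Oxt or Avp were fewer in the Sim1 heterozygous library. Lower depth as the whole cause is argued against, since in thinned cells the ratio of shares with at least 5 Avp UMIs was 0.274 [0.163 to 0.440]. For a loss of all PVN-type neurons alike, Crh and Trh together had a ratio of 1.01 [0.909 to 1.11], above the bound set for it. This rests on Crh (1.42 [1.22 to 1.64]), since 390 of 496 control Trh UMIs lay in the cluster led by Trh and Fezf1. Crh was not higher throughout: in the cluster led by Nrgn and Aldoc it had 111 and 31 UMIs. Summed UMIs measure level and not cell number, so they cannot decide on a loss of cells. In the cluster led by Crh and Nr3c1, 96 control and 98 Sim1 heterozygous cells had Crh at 1166 and 2020 CPM. Trh there went the other way, with 54 and 22 UMIs. A different piece of tissue or sort gate may have contributed, as the thalamus list, whose genes are not PVN genes, was at -1.37 [-1.57 to -1.16]. An effect of the Sim1 genotype, or of the sex of the pups, whose sex-linked genes also differed, stays open and untested. The same holds for the mix of ages in each pool and for the genetic background of pups from an outbred stock. All of these coincide with preparation in 1 library each.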
